A study of Mus musculus with 6 samples.

How the data were processed

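The study compared cortical cells of mouse embryos electroporated in utero with a plasmid for an shRNA against Nat14 (3 libraries) or for a control shRNA (3 libraries). Per the labels, plasmids were given at embryonic day 14.5, brains were taken 4 days later, and live GFP-positive cells were sorted into lysis buffer. RNA was isolated with a column kit and libraries were made with Nextera protocols. Groups and replicate numbers were taken from the sample titles.

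The data used were a table of the authors' own comparison, with a gene symbol and 4 values per gene. Per the file headers, these are a log2 fold change, a mean level as log2 CPM, a p-value and a false discovery rate, which is an adjusted p-value. The log2 values and p-values were deposited by the authors and were used as they stand. The submitters' processing notes name TopHat2 2.0.8, SAMtools 0.1.19, HTSeq 0.5.4p1 and DESeq, without saying which step each served, and the genome build hg19. That build is human, whereas the samples are mouse and the table holds mouse gene symbols, so the build behind the table is unresolved and no coordinates are given. The column names of the deposited table are those written by another count package than the one the notes name, so the authors' test is not known for certain. The authors' normalization and filters, and the prior count behind the fitted fold changes, are not given in the sources used here. The table gives no standard errors.

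The table holds 21937 symbols, of which 4537 sit at the lowest mean level (log2 CPM -3.09) and were left out of list tests, leaving 17400. In 25 rows the symbol had been turned into a calendar date by spreadsheet software, and these rows were kept in all counts and named nowhere. Symbols were matched to a RefSeq annotation of the mouse assembly GRCm38.p6, which was used for older symbols, for X and Y linkage and for the order of genes, and 21667 matched. The depth per library is unknown, so no interval or detection limit that needs it is given.

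Genes were called at the authors' adjusted p under 0.05. The genes named in the text follow a rule fixed before the data were examined. It takes Nat14, the 12 called genes with the largest rise and the 12 with the largest fall among those at or above the median mean level, the gene with the smallest adjusted p in each direction, and for each gene list up to 2 called members per direction, or the member with the smallest p where none was called. Only 9 rises and 7 falls met the level condition. The values of 1 of these genes and of 1 gene list are not reported here. Other genes named, such as Apoe, Aldh1l1, C1qa, Ttr, Col1a2, Dlx1, Aldh1a1, Tsix and the Y-linked genes, were chosen after their values were seen. Pseudogenes and unnamed models were allowed to be left out by the rule, and none had to be.

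Lists of genes for cell types, the cytoskeleton, signalling, stress, metabolism and responses to shRNA were also fixed beforehand, 42 lists with 1332 entries. Of these entries 1279 matched by symbol, 31 by an older symbol and 22 not at all. Each deposited p-value was turned into a signed z with the sign of the fold change, and lists with at least 5 measured genes were tested with the cameraPR function of limma 3.58.1 in R 4.3.3 at a preset correlation of 0.01, two-sided, with Benjamini-Hochberg adjustment over 41 lists. Fisher's exact test, one-sided for each direction, compared called and other genes. The list test was tested on simulated z values for the 17400 genes of this comparison over 50 draws. In these, 94.5% of lists shifted by 1 SD were recovered and 0.75% of unshifted lists were called. The z values were simulated with the same correlation of 0.01 that the test presets. These rates therefore do not cover lists whose genes vary together more strongly. For the closing section, random lists were drawn within 100 ranks of mean level, X-linked and autosomal medians were compared over 2000 bootstrap draws, and members of the astrocyte and radial glia lists were compared by a two-sided permutation test with 100000 resamples. Other computations used Python 3.11.15, scipy 1.17.1, numpy 2.4.6 and pandas 2.3.3.

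Alternatives tried were other thresholds, adjustments and level filters, a fold change minimum, re-centred fold changes, a preset correlation of 0.05, a rank-based list test, and lists limited by level, by overlap or to genes that were not called. The planned filter at 10 and 50 in the unit of the table was applied as CPM, since the table holds log2 CPM. Fits per library that had been planned for a table with libraries were not used here.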

Results

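Neuronal progenitors of the mouse cortex were electroporated in utero at embryonic day 14.5 with a plasmid carrying a control shRNA (NTC) or an shRNA against Nat14 (shNat14), a gene named for the N-acetyltransferase family. Brains were collected at embryonic day 18.5, the cortical region was dissected and dissociated, and live GFP-positive cells were sorted by FACS for RNA sequencing. There were 3 shNat14 and 3 NTC libraries. The labels do not say whether the libraries of a group came from separate embryos or litters, so the p-values measure only the spread between these libraries, which may be technical. The file used here is the authors' own comparison of the groups, with 21937 gene symbols and no values per library, so the depth of each library is unknown and the values below carry no SD. Fold changes are given as shNat14 relative to NTC, a direction that the column names do not state and that was read from the negative sign of the shRNA's target.

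The comparison asked which genes differed in level between cortical cells that received the Nat14 shRNA and those that received the control. In the authors' deposited table Nat14 was lower in shNat14, with a log2 fold change of -3.31, which is 10.05% of the control level (adjusted p = 1.2e-08). Because the direction of the table was read from this gene, its sign is no independent check of the library labels. In all, 34 genes were called at adjusted p under 0.05 in the authors' deposited table, 12 higher and 22 lower in shNat14. Of these, 16 had a mean level at or above the median of all genes, a log2 CPM of 1.71, and the other 18 lay below it.

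Among the calls at or above the median level, 9 were higher in shNat14. The rise with the smallest adjusted p in the authors' deposited table was that of the zinc finger gene Zfp318 (log2 fold change 2.42, adjusted p = 1.2e-08). Aldh1a7, of the aldehyde dehydrogenase family, had the largest rise of the 9 in the authors' deposited table, 7.41 on the log2 scale (adjusted p = 2.96e-08). At its mean log2 CPM of 2.70, a rise of this size puts NTC at a very low level, so the size depends on the prior count. Aldh1a1, the close paralog of Aldh1a7, stood at -0.88 in the authors' deposited table and was not called (unadjusted p = 0.291). The values of both are uncertain to the extent that reads were shared between them. Xist, the noncoding RNA that coats the inactive X chromosome, rose by 5.12 on the log2 scale in the authors' deposited table (adjusted p = 0.0112). Its antisense partner Tsix had a log2 fold change of 5.34 in the authors' deposited table, and without a statement that counting used strand, reads of this pair cannot be told apart. Ptchd1, an X-linked gene with a patched domain, rose by 2.69 and Stx3, a syntaxin of membrane fusion, by 2.22 on the log2 scale in the authors' deposited table. The authors' deposited table also listed rises of 1.95 for Tmf1, a Golgi protein, 1.56 for Glo1, the glyoxalase that clears methylglyoxal, 1.23 for Sel1l, an adaptor of endoplasmic reticulum-associated degradation, and 1.19 for the zinc finger gene Zfp120.

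The other 7 calls at or above the median level were lower, Nat14 among them. Tmem14c, a mitochondrial membrane protein of haem synthesis, had the largest fall of the 7 in the authors' deposited table, with a log2 fold change of -4.83 (adjusted p = 2.69e-07). Adora2b, an adenosine receptor, had a log2 fold change of -2.94 in the authors' deposited table, and Cwc22, a splicing factor, had -2.74 (adjusted p = 1.88e-08 for Cwc22). The zinc finger gene Zfp146 stood at -2.73 and Gps1, a subunit of the COP9 signalosome, at -1.46 in the authors' deposited table. Zinc finger genes form a large family of similar sequences, so the values of Zfp318, Zfp120 and Zfp146 are uncertain to the extent that reads were shared with other members.

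**Figure D1:**
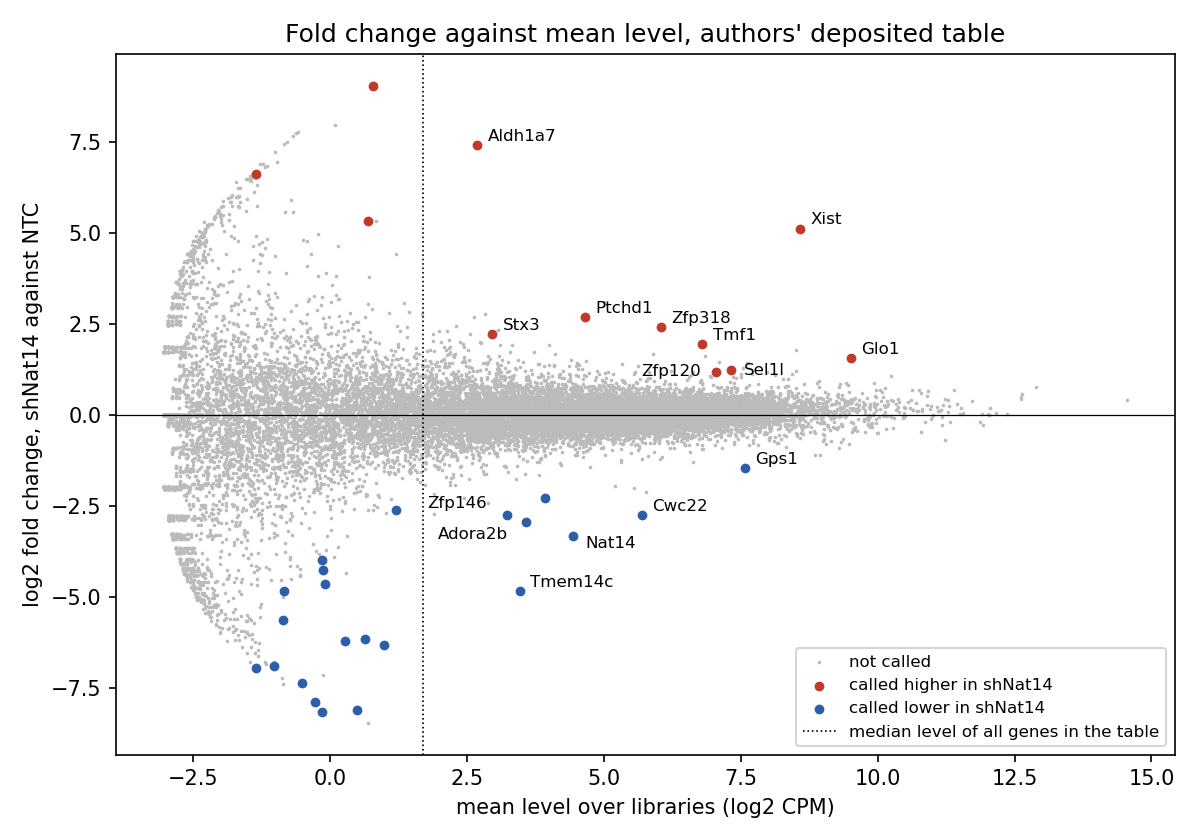
Log2 fold change of shNat14 against NTC (vertical axis) against mean level in log2 CPM (horizontal axis) for the 17400 genes above the lowest level in the authors' deposited table, with each point a gene and the dotted line the median level of all 21937 genes. Of the 16 called genes at or above that line 15 are named, Nat14 lying at -3.31, and the fold changes of genes that were not called spread more widely toward low levels.

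The remaining 18 calls lay below the median level, 3 higher and 15 lower, with absolute log2 fold changes from 2.60 to 9.04 in the authors' deposited table. At these levels a fitted fold change depends on the prior count and bounds nothing. Across all 34 calls, 35.3% were higher (exact 95% binomial interval 19.7 to 53.5%), a split that did not differ from even in a two-sided exact binomial test (p = 0.121), with genes that are not independent replicates. Among the 16 calls at or above the median level, 9 higher and 7 lower calls gave p = 0.804 in the same exact test. Over the 17400 genes above the lowest level, Spearman's rho across genes between absolute log2 fold change and mean level was -0.449, and that of the signed fold change was 0.083. The calls were 17, 9 and 8 in the tertiles of lowest, middle and highest mean level. Unadjusted p was under 0.05 for 648 of the 10969 genes at or above the median level in the authors' deposited table, where 548 would be expected by chance.

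Sex-linked genes were examined beside Xist. The 4 Y-linked genes Ddx3y, Uty, Kdm5d and Eif2s3y had a median log2 fold change of -1.09 in the authors' deposited table, none of them called (unadjusted p from 0.291 to 0.582). Of the 34 called genes, 6 were X-linked, and 28 calls were left without genes of the X and Y chromosomes, an alternative chosen after the data were seen. Among all genes at or above the median level, 411 were X-linked and 10467 autosomal. Of the 6 X-linked calls, which were counted at all levels, only Xist and Ptchd1 belong to that set. The X-linked share of calls was not tested. Beside the rises of Xist, Ptchd1 and Frmpd4, the X-linked calls held falls of Zcchc16 (-7.88), Gucy2f (-4.82) and Pou3f4 (-2.60) in the authors' deposited table. These falls and the rise of Frmpd4 (mean log2 CPM 0.70) lay below the median level.

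Markers of cell types were compared as lists fixed before the data were examined. Of 41 lists tested with camera on signed z values from the authors' p-values, 5 passed at adjusted p under 0.05. The astrocyte list was lower in shNat14 (adjusted p = 1.25e-08, median log2 fold change -0.50). Of its 18 measured genes, 17 had a negative fold change in the authors' deposited table, 1 was called lower and 3 were lower when adjusted over the list alone. The called member was Agt, angiotensinogen, with a log2 fold change of -6.33 at a low level in the authors' deposited table (adjusted p = 6.99e-06). In all 6 genes of the list had an unadjusted p under 0.05, all lower, and the smallest among those not called in the authors' deposited table were of Apoe, the main lipid carrier of the brain, at -1.10 (p = 0.00021) and Aldh1l1, a folate enzyme used as an astrocyte marker, at -1.15 (p = 0.00426). Without Agt the list still passed (adjusted p = 7.58e-06). The radial glia list, of which 1 gene is also in the astrocyte list, did not pass (adjusted p = 0.761). Of its 30 genes none was called, and Notch2 had the smallest p in the authors' deposited table (log2 fold change 1.04, p = 0.023).

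The microglia list was also lower (adjusted p = 2.91e-05, median log2 fold change -0.81). Of its 20 genes, 16 had a negative and 4 a positive fold change in the authors' deposited table. None of the 20 was called and 1 was lower when adjusted over the list alone, while 6 had an unadjusted p under 0.05, all lower. The complement genes C1qb and C1qa had log2 fold changes of -1.62 (p = 0.00169) and -1.42 (p = 0.0103) in the authors' deposited table. The related complement gene C1qc did not follow them and stood at 0.25 in the authors' deposited table, at a mean log2 CPM of 0.91. The list of choroid plexus and ependyma was higher (adjusted p = 0.00141, median log2 fold change 1.18), with 14 of 16 genes positive, none called, none passing when adjusted over the list alone and 2 at unadjusted p under 0.05. Dynlrb2, a dynein light chain, had the smallest p of this list in the authors' deposited table (log2 fold change 1.48, p = 0.0174). Ttr, transthyretin, the most abundant of these genes, stood at 1.80 in the authors' deposited table (p = 0.065).

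Meningeal fibroblast genes were lower as a list (adjusted p = 0.0133, median log2 fold change -0.47), with none of 18 called, none passing when adjusted over the list alone and 3 at unadjusted p under 0.05. Serping1 had the smallest p there (log2 fold change -0.83, p = 0.0355), and Col1a2, a fibrillar collagen, stood at -1.02 in the authors' deposited table. Interneuron genes were lower as a list at adjusted p = 0.0459, with a median log2 fold change of -0.33, none of 20 called, none passing when adjusted over the list alone and 5 at unadjusted p under 0.05. The transcription factors Dlx5 and Dlx1 stood at -0.76 and -0.79 in the authors' deposited table (p = 0.0134 and p = 0.0137). At a preset correlation of 0.05 the meningeal (adjusted p = 0.108) and interneuron (adjusted p = 0.208) lists no longer passed, whereas the astrocyte, microglia and choroid plexus lists did. The interneuron list was also lost in a rank-based test (adjusted p = 0.16), and the meningeal list when limited to genes in no other list (adjusted p = 0.247). A correlation between genes could not be estimated, since that needs values per library.

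**Figure D2:**
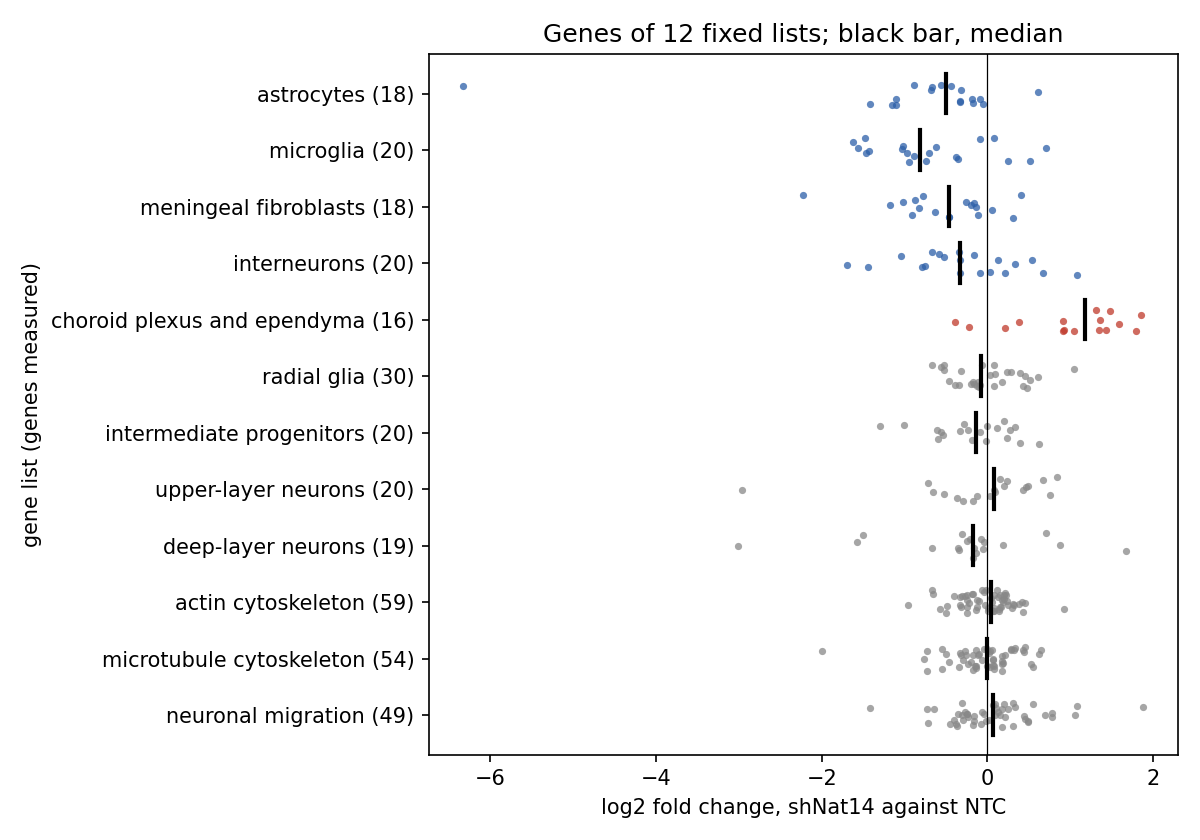
Log2 fold change of shNat14 against NTC (horizontal axis) for the genes of 12 lists fixed beforehand (vertical axis, with the number of genes measured), each point a gene from the authors' deposited table and each black bar the list's median. Blue lists were lower and the red list was higher at camera adjusted p under 0.05, from a median of -0.81 for microglia to 1.18 for choroid plexus and ependyma, and the grey lists did not pass.

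The other 36 lists did not pass, with the smallest adjusted p of 0.0613 for erythroid genes. In these lists no gene was called, apart from Nat14 and Nat2 in the list of acetyltransferases and deacetylases. Nat2, an arylamine N-acetyltransferase, had a log2 fold change of -6.19 at a low level in the authors' deposited table (adjusted p = 0.00131), and 3 of the 49 genes of that list were lower when adjusted over the list alone (camera adjusted p = 0.193). Fisher's exact test on the calls gave 0 lists at adjusted p under 0.05 and 2 at unadjusted p under 0.05, acetyltransferases and deacetylases (p = 0.00173) and astrocytes (p = 0.0225), both for lower calls. Median, mean and camera statistic differed in sign in 11 lists, all among those that did not pass, among them radial glia, upper-layer neurons, DNA replication, actin, Notch, Wnt, presynaptic, ion channel, extracellular matrix and immediate early genes.

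Cytoskeletal genes, which the title of the series names, were covered by lists that included actin and microtubules, neither of which passed. Of 59 actin cytoskeleton genes, 3 had an unadjusted p under 0.05, all lower, and the membrane linker Ezr had the smallest in the authors' deposited table (log2 fold change -0.66, p = 0.0193). The camera adjusted p of the actin list was 0.761 and its median log2 fold change was 0.04. Of 54 microtubule genes, 3 had an unadjusted p under 0.05, and the tubulin Tubb2b stood at -0.73 in the authors' deposited table (p = 0.039). That list had a camera adjusted p of 0.761. The neuronal migration list (camera adjusted p = 0.761) had Flrt3 at 0.70 in the authors' deposited table (p = 0.0314), and the axon guidance list (camera adjusted p = 0.588) had Ntn1, netrin 1, at -2.60 (p = 0.000402), its single gene that was lower when adjusted over the list alone.

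Lists of neurons and their progenitors also did not pass. For intermediate progenitors (camera adjusted p = 0.283) Mfap4 stood at -1.29 in the authors' deposited table (p = 0.000243) and was the single gene lower when adjusted over the list alone. The smallest p was that of Etv1 among deep-layer genes (log2 fold change -0.67, p = 0.012) and of Pou3f3 among upper-layer genes (0.84, p = 0.0122) in the authors' deposited table. Their camera adjusted p-values were 0.312 and 0.761. Gap43 led the pan-neuronal list at 0.78 (p = 0.0114) and Nhlh2 the Cajal-Retzius list at 0.94 (p = 0.0694) in the authors' deposited table, with camera adjusted p of 0.688 and 0.761. Synaptic lists had Amph at 0.71 (p = 0.0212) on the presynaptic side and Camk2b at 0.99 (p = 0.0403) on the postsynaptic side in the authors' deposited table, with camera adjusted p of 0.817 and 0.612. Gabra4, a GABA receptor subunit, stood at 0.99 in the authors' deposited table (p = 0.000746) and was the single ion channel gene that was higher when adjusted over the list alone (camera adjusted p = 0.588).

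Among other cell types, the smallest p was that of Cnp in the oligodendrocyte lineage (-1.08, p = 0.0191), Emcn in endothelium (4.98 at a low level, p = 0.0137) and Acta2 in mural cells (1.86, p = 0.021) in the authors' deposited table. Camera adjusted p was 0.232, 0.0789 and 0.353 for these lists. The embryonic globin gene Hba-x led the erythroid list at -6.53, again at a low level, in the authors' deposited table (p = 0.00832). Only 10 of the 16 genes of that list were measured. The globin genes Hba-a1, Hba-a2 and Hbb-b2 sat at the lowest mean level and were left out of its test. Cell cycle lists had Mcm3 of DNA replication at -0.52 (p = 0.102), Cenpe of mitosis at 0.72 (p = 0.0156) and Cdk4 of the list on cell cycle exit at -0.52 (p = 0.0353) in the authors' deposited table. Their camera adjusted p-values were 0.788, 0.283 and 0.518. The centrosome and cilium list had Ift80 at 0.96 in the authors' deposited table (p = 0.0115, camera adjusted p = 0.106).

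Signalling lists had Hes6 of the Notch pathway at -0.65 (p = 0.0137) and Znrf3 of the Wnt pathway at 1.46 (p = 0.000123) in the authors' deposited table, Znrf3 being the single Wnt gene higher when adjusted over the list alone. Camera adjusted p was 0.761 and 0.688. Pcdh7 led the cell adhesion list at 0.82 (p = 0.0183) and Timp4 the extracellular matrix list at -1.56 (p = 0.000142) in the authors' deposited table. Adjusted over the list alone, 1 matrix gene was higher and 1 lower, and camera adjusted p was 0.588 for adhesion and 0.817 for matrix.

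Lists of stress and of responses to shRNA did not pass either. Cxcl10 of the interferon and double-stranded RNA response stood at 2.91 at a low level (p = 0.0165) and Plk2 of the p53 list at 0.86 (p = 0.00109) in the authors' deposited table, Plk2 being the single p53 gene higher when adjusted over the list alone. Camera adjusted p was 0.761 and 0.43. The smallest p was that of Eif2c1 (-0.55, p = 0.104) for microRNA and shRNA processing, Homer1 (0.78, p = 0.0809) for immediate early genes and Hsp90aa1 (0.68, p = 0.0495) for heat shock and the unfolded protein response in the authors' deposited table. These lists had camera adjusted p of 0.788, 0.937 and 0.588.

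Metabolic and translation lists had Rpl13 of the cytosolic ribosome at -0.30 (p = 0.244), Cox7c of nuclear-encoded oxidative phosphorylation at 0.76 (p = 0.0546), Slc16a1 of glycolysis and hypoxia at 0.69 (p = 0.0134) and Mvk of cholesterol synthesis at -1.20 (p = 0.00998) in the authors' deposited table. Camera adjusted p was 0.761, 0.937, 0.699 and 0.232 in that order. In the list of mitochondrially encoded genes 0 symbols were matched, so it was not tested.

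The number of called genes depended on the adjustment and the level of the genes. It was 16 when the deposited p-values were adjusted over genes at or above the median level and 17 after Bonferroni correction, and 8 of the 34 calls had a mean level of at least 50 CPM.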

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

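Alternatives without genes of the X and Y chromosomes, without neighbouring genes and without called list members were chosen after the data were seen. No paired analysis was possible because the table holds no values per library. For the same reason the replicate block, leaving out each library, other normalizations, count tests and count filters, pseudocounts, an estimated correlation between genes and other splits of the samples were not run, so it is unknown whether a single library decides any value. Against 34 called genes, 19 were called at adjusted p under 0.01, 55 under 0.1, 16 with Benjamini-Hochberg adjustment over genes at or above the median level, 13 at 10 CPM or more, 8 at 50 CPM or more and 17 with Bonferroni correction. These follow from the threshold or from the fewer genes included. The count was 28 without X and Y genes and 24 without genes within 20 genes of another at unadjusted p under 0.001. The share of higher calls, 35.3%, reversed to 56.25% with adjustment over genes at or above the median level, 53.85% at 10 CPM or more and 75% at 50 CPM or more. Each of these settings leaves out the 18 calls below the median level, of which 3 were higher and 15 lower. Why calls at a low level were mostly lower was not tested. Neither the main split nor the splits in these settings differed from even. Nat14 stayed lower and past the threshold in each alternative run. These only re-adjusted or re-centred its deposited values, so none could have failed. Re-centring shifted fold changes by 0.032. Of 5 lists past the threshold, 3 passed at a preset correlation of 0.05. Fisher's exact test gave 0 lists with calls at adjusted p under 0.05, 1 at 0.1 (astrocytes, adjusted p = 0.0228) and 1 at 0.01, acetyltransferases and deacetylases (adjusted p = 0.0244), which is not among the 5 and rests on Nat2 and the shRNA target Nat14. For the 5 lists, 21 of 25 alternatives stayed past the threshold, 4 did not and 0 reversed. Those 4 were interneurons at a correlation of 0.05 and in the rank-based test, and meningeal fibroblasts at a correlation of 0.05 and limited to genes in no other list (limma camera, adjusted p = 0.247). Some of the 21 could not fail. Only the astrocyte list had a called member, so leaving out called members repeated the main test for the other lists. The limit to genes in no other list likewise left the microglia and choroid plexus lists unchanged. Spearman's rho of absolute fold change with level, -0.449, was -0.0801 at 10 CPM or more and -0.7192 over called genes, and the cause was not tested.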

Other observations

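Tests chosen after the result was seen were those of the female share, of the share of other cells in the sort, of neighbouring genes and inherited haplotypes, and the narrowed tests of the 3 lists written after the table had been seen.

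Several of the 18 calls at a low level, chosen here after their values were seen, belong to genes of antigen presentation and lymphoid cells. Cd74 and H2-Ab1, of MHC class II, had log2 fold changes of -4.62 and -4.24, the B-cell adaptor Blnk had -6.88 and Rgs1, a regulator of G-protein signalling in immune cells, had -6.16 in the authors' deposited table. In the other direction, Ostn, osteocrin, had 9.04 in the authors' deposited table (adjusted p = 4.18e-08). The motile cilia genes Mlf1 and Lrriq1, also chosen after their values were seen, stood at 1.69 (adjusted p = 0.0713) and 2.30 (adjusted p = 0.114) in the authors' deposited table, neither of them called.

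From such genes 3 hypotheses on cell composition were drawn, each with its own list. The ventral list below was at first dropped because its result was seen to be near null, and it was restored afterwards, so the choice of what to report was not made blind to the outcome. The tests as first written left out called genes, or for motile cilia the genes of the fixed list, but still held genes that had prompted the lists, namely Cd69, Foxb1, Mlf1 and Lrriq1, and so decide nothing by themselves. Their mean signed z was -1.21 over 10 MHC class II and B-cell genes, 1.36 over 18 motile cilia genes and -0.311 over 14 ventral and hypothalamic genes. A narrowed test, added after values had been seen, also left out members with an unadjusted p under 0.001 and with them those prompting genes.

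In the narrowed test the MHC class II and B-cell list had a mean signed z of -0.916 over 9 members (limma camera, adjusted p over the 3 lists = 0.0121). Of these, 6 were lower, 2 were higher (H2-Eb1 and Cd79b) and Ciita had a signed z of 0. The result rests on H2-Aa, the partner of the called H2-Ab1, with a log2 fold change of -4.27 at a low level in the authors' deposited table. Without H2-Aa, an alternative also chosen after the data were seen, the list no longer passed (mean signed z -0.653, limma camera adjusted p = 0.103), so fewer B cells or antigen-presenting cells in shNat14 stays undecided. No member of that list is in a fixed list or reaches the median level, the most abundant being H2-DMa (log2 CPM 1.04, log2 fold change -0.52, p = 0.436 in the authors' deposited table), and a gate on GFP-positive cells would be meant to remove such cells. Motile cilia genes outside the fixed list had 1.07 over 16 genes (limma camera, adjusted p = 0.000769), with 13 higher and 3 lower, the latter Rsph9 (-0.60), Hydin (-0.56) and Dnaic1 (-0.08) in the authors' deposited table, so more cells with motile cilia may lie behind the higher choroid plexus and ependyma list. That list was written after the table had been seen and its p was adjusted over 3 such lists alone, so this is a hypothesis without independent evidence, and the cortical dissection and the GFP gate would be meant to remove choroid plexus cells. Fewer cells of ventral or hypothalamic origin, drawn from Six3os1, Foxb1 and Pou3f4, was not backed, at -0.044 over 13 members (limma camera, adjusted p = 0.77), and the cortical dissection and the GFP gate would be meant to remove such cells. Tests that leave out the called genes exclude nothing, so that hypothesis stays undecided too.

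Xist was 34.8-fold higher in shNat14 in the authors' deposited table. Xist switched on with silencing of an active X chromosome is argued against. The median of 411 X-linked genes at or above the median level lay 0.0652 above that of autosomal genes (95% bootstrap interval 0.00663 to 0.103). Silencing would lower it. Xist switched on without silencing would leave that median unchanged, so it stays open. The interval measures the spread between genes, not between libraries. A larger share of female embryos behind the shNat14 libraries is consistent with the Y-linked median of -1.0886 and with a median of 0.54 for 4 X-linked genes that stay active on both X chromosomes, although no Y-linked gene had an unadjusted p under 0.29 and 1 of the 4 X-linked genes, Eif2s3x, stood at -0.36 in the authors' deposited table. On a simple mixture of cells, the Xist and Y-linked values would need 1.54% female cells in NTC and 53.7% in shNat14, which implies 0.60 for those X-linked genes. Without values per library, whether this follows the groups or a single library stays open.

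Markers of astrocytes and microglia were lower in shNat14 and those of choroid plexus and ependyma higher in each alternative list test run with camera, whereas the lower meningeal fibroblast and interneuron lists were lost in some (adjusted p = 0.108 and 0.208 at a preset correlation of 0.05). A lower share of all other cells in the sort is not decided by the mean signed z of 1.137 for the choroid plexus and ependyma list. That test was chosen after the rise was seen, and whether the ependyma genes mark cells outside the electroporated lineage is not known here. The endothelial and mural lists also had positive mean signed z (0.678 and 0.498) but did not pass (limma camera, adjusted p = 0.0789 and 0.353). The microglia, meningeal fibroblast and erythroid lists had negative mean signed z. For the astrocyte list, a trend of fold change with level is argued against, since 0.0% of 10000 random lists matched on mean level had a median as low. The members of the astrocyte and radial glia lists alone differed in mean signed z by -1.5951 (permutation p = 6e-05), or -1.32 without Agt. The fall therefore did not extend to the radial glia list. As the lists share only 1 gene, this does not decide whether genes that both cell types express fell. Both comparisons treat genes as independent. The permutation p measures the spread between genes, not between libraries, and may be too small where markers vary together. Still open and untested are an effect of the knockdown and a difference in dissection or sorting between the groups, with the limit that a gate on GFP-positive progeny of electroporated progenitors would be meant to remove microglia, meningeal fibroblasts, choroid plexus cells and interneurons, which arise from ventral progenitors.

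Genes at unadjusted p under 0.001 lay near each other in 16 pairs within 20 genes, among them Tlr7 with Frmpd4 and Htr7 with Myof. Reads shared between the genes of a pair as tandem paralogs could explain few pairs, as 6.25% of the pairs were of like-named or overlapping genes. A gene that shared reads with a paralog outside this set would be missed, so shared reads in general stay undecided. Inherited haplotypes that differ between the embryos could give such pairs, but the other 15 pairs stood against a median of 10 in 10000 permutations matched on level (one-sided permutation p = 0.0995), so haplotypes and chance cannot be told apart with this few pairs.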
